A study of Caenorhabditis elegans with 2 samples.

How the data were processed

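The deposited processed peak lists of the authors were used, on ce11 for every comparison and on ce10 for counts and chromosome shares only. Per the labels, the strain was RW10316, the tissue was the whole organism, and chromatin was sheared by sonication. Per the labels, the description names anti-GFP, while the antibody tag names die-1, and the first was used in the text. The control the authors used was not analysed here. Reads, signal tracks and quality files were not used here. The peak caller, its version, the aligner and the IDR threshold are not given in the sources used here.

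The signal column of the deposited peak lists was read as the authors' own enrichment value for the peak, in its original unit and without change except log10 where stated. The q-value column was read per the file layout of the authors as −log10 of the q-value. It reached 2.414 at most in the reproducible list, so peaks were ranked by signal. The summit offset of the deposited lists was read as the distance in bp from the peak start. The list of reproducible peaks was made by the authors from both replicates, and each relaxed list is as the authors gave it. Merging overlapping reproducible peaks gave 1395 regions.

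Positions were placed on WBcel235, the Ensembl name of ce11, with Ensembl 115 gene models. Of 2811 genes without a name there, 2767 took a name from RefSeq by position. Calculations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

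The tests, thresholds, gene lists, motifs, windows and rule for naming genes were set before the data were examined. The rule named the protein-coding gene with the nearest transcript start for the 25 strongest reproducible peaks, with position for the first 10. It also named up to 4 members with a peak per gene list, the genes die-1 and unc-119, each motif past the threshold, and the 10 words of 6 bases with the smallest p. The snoRNA, snRNA and other RNA classes, the feature shares, the offsets from 5' ends, the longer words and every comparison without peaks at short RNA genes or mitochondrial peaks were added after the data had been seen.

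A gene counted as having a peak when a reproducible summit lay from 1000 bp upstream to 300 bp downstream of a protein-coding transcript start, or within 200 bp for RNA genes. Circular shifts moved all summits along each chromosome 10000 times, with a smallest two-sided p of 0.0002 and a smallest one-sided p of 0.0001. Permutations numbered 100000, with a smallest p of 1e-05. The threshold was an adjusted p of 0.05 by Benjamini-Hochberg within each family, over 28 gene lists, 15 motifs, 2080 words of 6 bases or 25 feature tests. Gene lists were drawn up from general knowledge of the worm, every entry matched a gene, and lists needed 5 members to be tested. Odds ratios of the gene lists had 0.5 added to each cell. Motif windows were 101 bp around the summit, and control windows of the same width lay 300 bp to one side. Intervals of shares are 95% Wilson intervals.

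Alternatives tried were narrower (500 and 100 bp) and wider (2000 and 500 bp) promoter windows, the 50% of peaks with the highest signal, merged peaks, and each replicate list alone. Further alternatives were other summit distances, the other flank, wider motif windows, shuffled windows, relaxed peaks as the background, the nearest start, gene starts in place of length, and the ce10 list.

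On simulated input, the promoter test called 8% of random placements and 100% of those with 10% of summits moved into promoters. Simulated lists of 80 genes at the background share were called at an unadjusted p of 0.05 in 0.5% of draws, and at 4 times that share in 95%. With no planted word of 6 bases 0 words were called, and with 1 planted word it had the smallest p among 8 called.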

Results

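DIE-1 is a zinc finger transcription factor that is needed for shape changes of the embryonic epidermis and for left and right differences between the ASE taste neurons. Per the labels, a transgenic C. elegans strain carried DIE-1 fused to GFP, and chromatin of whole young adult hermaphrodites was taken with an anti-GFP antibody 64 hours after synchronization. The series held 1 group with 2 biological replicates, so no group contrast existed. The peak lists were those of the authors, and the signal printed for each peak is the authors' own enrichment value, whose exact scale is not given in the sources used here. Peaks or genes were the units of the tests below, and neither are replicates. One summit can count for several genes: 570 promoter summits gave 676 protein-coding genes with a peak. The Fisher tests of genes treat such genes as independent, which they were not in full.

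The strongest peaks lay on the mitochondrial genome, and the strongest nuclear peaks lay beside snoRNA genes. On the mitochondrial genome, the peak nearest the start of CYTB, which codes for cytochrome b, had the highest signal (5177, M:4212-5464). The peak nearest ND5, a gene for an NADH dehydrogenase subunit, followed with 5129 (M:12107-12723). COX3, a cytochrome c oxidase gene, was nearest the peak with signal 3562 (M:5813-6410). Peaks nearest COX1 had 2592 (M:6944-7492) and 1677 (M:8044-8966), and peaks nearest COX2 had 2338 (M:9951-10372) and 1675 (M:8896-9361). The peaks nearest ND3 (1805, M:10646-11115), ND1 (1662, M:897-1466) and ND2 (1651, M:2806-3128) completed the first 10. The ATP synthase gene ATP6 (1640) and ND4 (1355) were also nearest to peaks among the first 25, of which 17 were mitochondrial. Mitochondrial peaks were counted here but were left out of the positional tests, which used the 1411 nuclear peaks.

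The highest nuclear signal, 649, lay in an intron of the peroxidasin gene pxn-1 (V:8500390-8500737), 7 bp from the snoRNA gene ZK994.7. The snoRNA gene C51F7.4 lay under the summit of the next nuclear peak (533.6), in an intron of frm-7 and nearest to the start of F55C5.17. Peaks beside snoRNA genes were nearest to pamn-1 (503.4), cec-4 (466.4), str-56 (462.4), W03C9.1 (447.1) and Y75B12B.11 (419.4). The peak at rpl-3 (-294 bp from the start), which codes for a protein of the large ribosomal subunit, had a signal of 437.2 and was the only nuclear peak of the first 25 away from any short RNA gene. The reproducible list held 1432 peaks, with a median signal of 115.5 and a median width of 436 bp. The relaxed lists held 30000 peaks for the pooled reads, 23789 for replicate 1 and 29268 for replicate 2. All 1432 reproducible peaks were the pooled peaks of highest signal, and the lowest of them had 79.4.

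Peaks of both replicates met at the same places, and the peak at pxn-1 was strong in both, with a signal of 259.2 in replicate 1 and 391.5 in replicate 2. At CYTB the values were 2528 and 2711, and at rpl-3 they were 194.2 and 246.3. Of the 1432 strongest replicate 1 summits, 978 (68.3%) had one of the 1432 strongest replicate 2 summits within 200 bp. Circular shifts of the summits gave 1.23% on average and 10.6% at most (one-sided shift permutation p = 0.0001, the smallest that 10000 shifts can give). Away from short RNA genes and mitochondrial DNA, 463 of 881 summits (52.6%) were shared, against 0.362% under shifts. Over 1429 reproducible peaks the replicate signals had a Spearman correlation of 0.643 and a Pearson correlation of log10 signal of 0.811. No p is given for these correlations, because the peaks were chosen by the pooled signal of the same reads and some summits shared a replicate peak, such as 2 nearest CYTB. Across the 860 peaks away from short RNA genes and mitochondrial DNA, which include rpl-3, the Spearman correlation was 0.294.

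**Figure D1:**
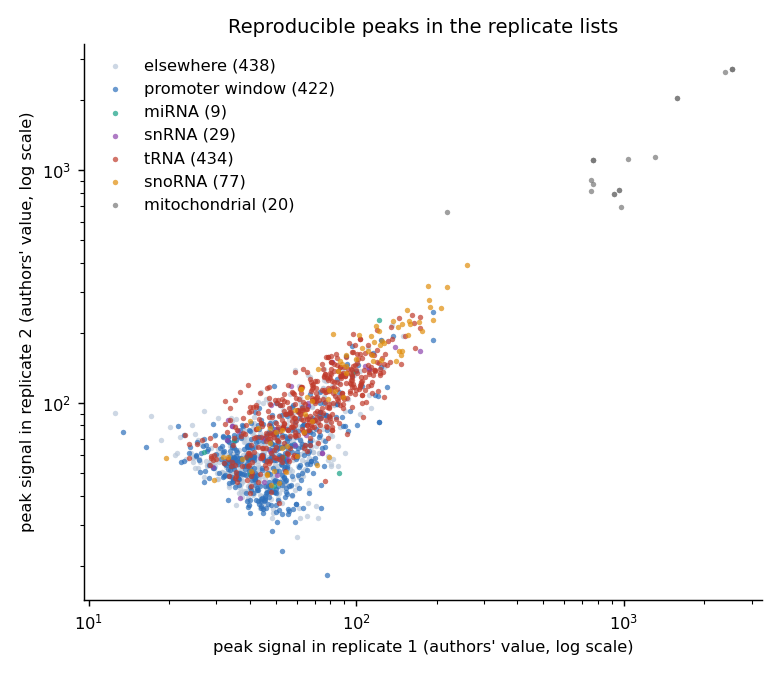
Signal of each reproducible peak in replicate 1 and replicate 2, by the class of gene at the summit. The Spearman correlation over 1429 peaks was 0.643.

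tRNA genes held more nuclear peaks than any other class of short RNA gene. Of 1411 nuclear summits, 434 (30.8%, 95% interval 28.4 to 33.2) lay within 200 bp of a tRNA gene, against 0.311% under circular shifts (two-sided shift permutation p = 0.0002, the smallest the shifts can give). The strongest tRNA peaks lay on X, at M02F4.t1 (402.6) and at W03G11.t1 (397.7). Counted by gene, 472 of 612 nuclear tRNA genes (77.1%) had a summit within 200 bp. In the replicate 1 list of the same length 435 tRNA genes had a summit, and in the replicate 2 list 475. Genes for tRNA-Asp (25 of 27), tRNA-Glu (36 of 41), tRNA-Leu (34 of 39) and tRNA-Lys (40 of 46) had the largest shares. tRNA-His genes (12 of 20) and tRNA-Arg genes (28 of 44) had smaller shares, and the 1 tRNA-Sec gene had no peak. None of the 22 tests passed the threshold, 1 of which took the genes without an assigned isotype. The smallest Fisher adjusted p was 0.239 for those genes (1 of 5 with a peak) and 0.4175 among assigned isotypes. tRNA pseudogenes differed from tRNA genes, with peaks at 11 of 209 (odds ratio 60.7, two-sided Fisher adjusted p = 6.29e-81). Summits lay a median of 12 bp downstream of the 5' end of the tRNA gene, with quartiles at -1 and 43 bp.

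Classes of short RNA gene other than tRNA were chosen after the data had been seen. Genes for snoRNA, which guide chemical changes of ribosomal RNA, had 77 summits within 200 bp (5.46%, against 0.179% under shifts, two-sided shift permutation adjusted p = 0.000313 over 25 feature tests). By gene, 77 of 346 snoRNA genes (22.2%) had a peak, with 36 of 183 inside a protein-coding gene on the same strand and 41 of 163 elsewhere (two-sided Fisher p = 0.245). Summits at snoRNA genes lay at a median of -36 bp from the 5' end, on the upstream side. Among snRNA genes, sls-2 genes for the SL2 spliced leader, which caps downstream messages of operons, had peaks at 8 of 18 (1 of them, sls-2.9, by a summit inside a tRNA gene), with 309 at sls-2.4 and 230.8 at sls-2.1. The sls-1 genes for the SL1 leader had peaks at 0 of 12, and whether reads can be placed uniquely at these neighbouring genes was not checked. The RNase P RNA gene rpr-1, whose product trims tRNA precursors, had a signal of 344.1, and the RNase MRP RNA gene mrpr-1 had 250.1. The Y RNA gene yrn-1 had 147.4. Of 5 genes for the RNA of the signal recognition particle, 4 had a peak: srpr-2.1 (189.3), srpr-2.2 (116), srpr-1.2 (106.4) and srpr-1.1 (79.5). The long RNA genes tts-1, tts-2 and rncs-1 had no peak. The broad ncRNA class, which includes rpr-1, mrpr-1 and yrn-1, was within 200 bp of 445 summits (31.5%, against 3.69%, shift permutation adjusted p = 0.000313). Only 128 of these 445 lay away from short RNA genes, and the rest were summits already counted at such genes. lincRNA genes were near 12 summits (0.850%, against 0.320%, shift permutation adjusted p = 0.0102).

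Nearby miRNA genes were found for 9 summits (0.638%, against 0.123%, shift permutation adjusted p = 0.000526). piRNA genes, which make germline guide RNAs, were within 200 bp of 1.21% of summits, below the 2.83% under shifts (adjusted p = 0.000526). tRNA pseudogenes were near 0.780% of summits, above the 0.0866% under shifts (shift permutation adjusted p = 0.000313). The pseudogene class of the gene models was near 1.63% of summits, below the 3.62% under shifts (shift permutation adjusted p = 0.000526). rRNA genes of the nuclear genome had no peak at any of 20, and whether reads can be placed uniquely there was not checked. Among the 100 strongest pooled peaks, 32% lay at tRNA genes, 34% at snoRNA genes and 20% on mitochondrial DNA. Ranks 101 to 200 had tRNA genes at 72%, and ranks 1001 to 1432 had them at 8.1%.

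**Figure D2:**
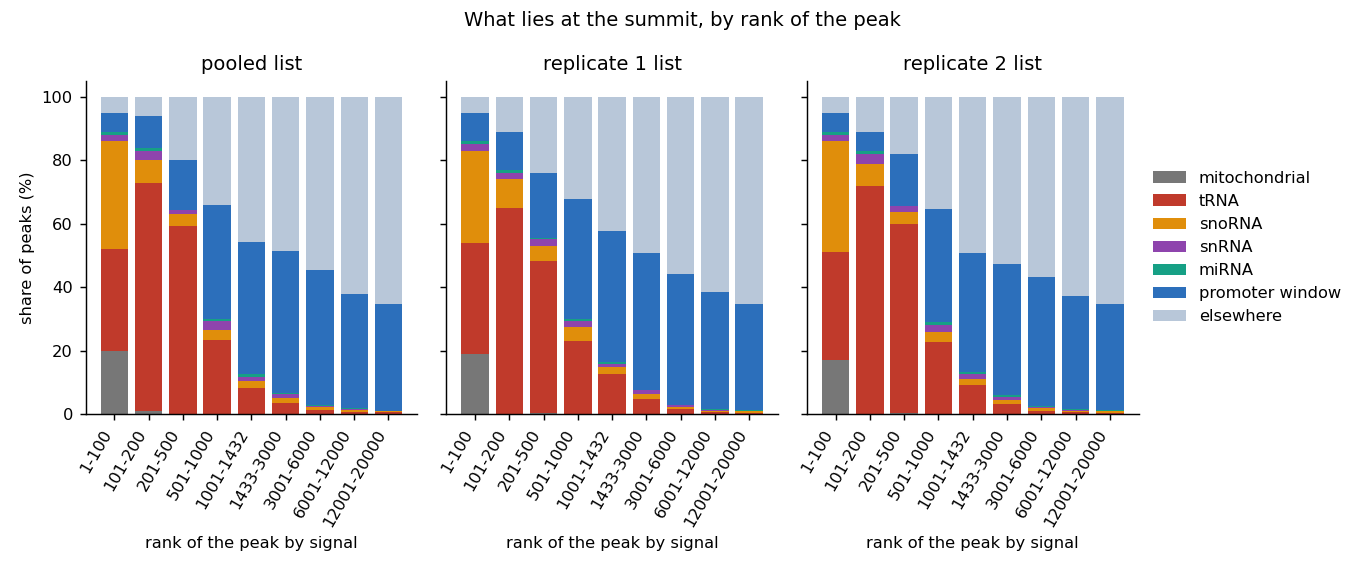
Share of pooled peaks in each class of gene at the summit, by rank of signal. tRNA genes had 72% of ranks 101 to 200.

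**Figure D3:**
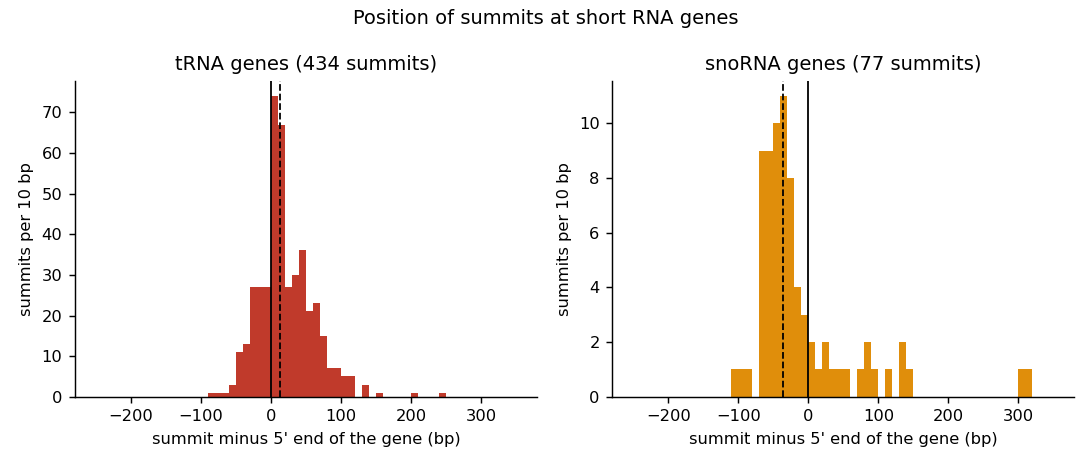
Distance of summits from the 5' end of tRNA genes and snoRNA genes. The medians were 12 bp for tRNA genes and -36 bp for snoRNA genes.

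Outside short RNA genes, the strongest promoter peaks lay at rpl-3 (437.2), at the threonine aspartase gene tasp-1 (379.4, -57 bp from the start), at K12H4.5 (336.7) and at the ribosomal protein gene rpl-15 (285.4). The peak at cdc-48.1, which codes for a segregase of the protein degradation system, had 231.8. Summits lay from 1000 bp upstream to 300 bp downstream of a protein-coding transcript start for 570 of 1411 peaks (40.4%, 95% interval 37.9 to 43.0). Circular shifts gave 27.3% (fold 1.48, two-sided shift permutation p = 0.0002, the smallest the shifts can give). Against relaxed peaks as the background, 35.6% of which lay in promoters, the fold was only 1.13. Away from short RNA genes, 423 of 862 summits (49.1%) lay in promoters, against 27.6% under shifts (two-sided shift permutation adjusted p = 0.000313) and 35.7% of relaxed peaks (fold 1.37). Of these 862 summits, 128 (14.8%, against 3.41% under shifts) still lay within 200 bp of ncRNA genes such as rpr-1. Coding exons held 8.35% of these 862 summits, against 24.7%, and introns held 18.8%, against 34.1% (shift permutation adjusted p = 0.000313 for each). The 3' UTR held 11.1%, against 3.70% (shift permutation adjusted p = 0.000313). These parts of genes were not kept apart from promoter windows, so a summit can count in both.

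Signal in promoters had a median of 108.3, and signal of all other nuclear peaks had a median of 118.9 (difference of median log10 signal -0.0404, two-sided permutation p = 0.00049). Without peaks at short RNA genes the medians were 100.9 and 99.4, and the direction turned (difference 0.00676, permutation p = 0.477). In the 50% of peaks with the highest signal, the difference was -0.0277 (permutation p = 0.068).

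Ribosomal protein genes carried promoter peaks more often than other genes. Signal at rpl-20 was 250.2 and at rpl-35 186.8, next to the values at rpl-3 and rpl-15 given above, and 19 of 76 ribosomal protein genes (25%) had a summit in the promoter window. Other protein-coding genes had 3.30% (log2 odds ratio 3.31, two-sided Fisher adjusted p = 1.58e-10 over 28 lists). Against genes with a relaxed pooled peak the log2 odds ratio was 2.10 (Fisher adjusted p = 6.50e-05). When each summit counted only for the nearest start in the window, 11 of 76 (14.5%) were left (log2 odds ratio 2.70, Fisher adjusted p = 7.50e-05). Some of these summits were thus nearer to another gene, such as the rpl-20 summit, which was nearest to the start of Y17G9B.5 (-179 bp). Without peaks at short RNA genes, 18 ribosomal protein genes kept a peak. Translation factor genes had peaks at 5 of 31 (log2 odds ratio 2.57, Fisher adjusted p = 0.0334), led by eif-2Bgamma (131.6), eef-1A.2 (128.6), eif-3.C (103.4) and eef-1A.1 (89.3). The translation factor call lay near the threshold. It was stronger in the replicate 1 list alone (7 of 31, log2 odds ratio 3.12, Fisher adjusted p = 0.000653). It held with merged peaks (Fisher adjusted p = 0.0328), the narrow and wide windows (0.0461 and 0.0348) and the nearest start at any distance (0.0463). It ended in the replicate 2 list alone (log2 odds ratio 1.89, Fisher adjusted p = 0.306), without peaks at short RNA genes (2.21, 0.183) and in the 50% of peaks with the highest signal (2.52, 0.522). It also ended against genes with a relaxed pooled peak (1.53, 0.697) and with the nearest start in the window (2.58, 0.0837). Chemoreceptor genes, which act in sensory neurons, had fewer peaks than other genes, at 11 of 1283 (log2 odds ratio -2.03, Fisher adjusted p = 4.45e-08). Among them were sre-23 (411), srh-269 (213.6), srd-44 (154.9) and srh-2 (128.4), of which the first 3 had their peak at a short RNA gene. Without such peaks 6 of 1283 were left, and the list was still called as lower (Fisher adjusted p = 7.66e-08). The chemoreceptor call ended when only genes with a relaxed pooled peak formed the background (log2 odds ratio -0.30, Fisher adjusted p = 1).

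Counts at genes tied to the known roles of DIE-1 were too small to tell their share of peaks from that of other genes. Of 38 genes for epidermal morphogenesis, the junction gene ajm-1 (148.7) was the only one with a peak (2.63%, upper 95% limit 13.5%, against 3.39% of other genes, Fisher adjusted p = 1). That summit lay at a short RNA gene, and without such peaks the list had 0 of 38. ASE neuron asymmetry genes had 0 of 28, with an upper 95% limit of 12.1%. Seam, timing and molting genes also had 0 of 28. Cuticle collagen genes had 2 of 175, at col-185 (234.7, at a short RNA gene) and col-181 (83.4) (Fisher adjusted p = 0.476). They had 5 of 175 in the replicate 1 list alone and 1 of 175 in the replicate 2 list alone, without a call in either. Homeobox genes had 2 of 63, at ceh-2 (179.7) and ceh-43 (101.9), both at short RNA genes, and without such peaks 0 of 63. Nuclear hormone receptor genes had 7 of 269, led by nhr-255 (197.4), nhr-68 (147.2), nhr-41 (140.7) and nhr-1 (107.2), and 4 of 269 without peaks at short RNA genes.

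Heat shock protein genes with peaks were hsp-60 (174.3), hsp-3 (142.2) and hsp-1 (92.0), 3 of 21 (Fisher adjusted p = 0.183), and the list was called in the replicate 1 list alone (adjusted p = 0.029). Core histone genes had 5 of 50, led by his-37 (142.7), his-60 (121.7), his-59 (110.5) and his-67 (89.7) (Fisher adjusted p = 0.183). The histone list was called in the replicate 2 list alone (6 of 50, Fisher adjusted p = 0.048) and in the replicate 1 list alone (6 of 50, adjusted p = 0.033). Vulva and somatic gonad genes had 2 of 25, at the growth factor gene egl-17 (279, at a short RNA gene) and the netrin receptor gene unc-40 (92.4). Wnt signalling genes had 2 of 27, at lit-1 (97.8) and mig-5 (96.2). Body muscle genes had 2 of 29, at unc-60 (96.1) and act-4 (89.2). The germline helicase gene cgh-1 (96.3) was 1 of 43, the proton pump gene vha-1 (96.9) was 1 of 11 excretory canal genes, and the kinase gene akt-2 (110.1) was 1 of 13 insulin signalling genes. Germline genes had 3 of 43 in the replicate 2 list alone and 2 of 43 in the replicate 1 list alone, without a call in either. With the wide promoter window insulin signalling had 4 of 13 (Fisher adjusted p = 0.0347), and with the nearest start at any distance it also had 4 of 13 (adjusted p = 0.035). Detoxification genes had 2 of 141, at cyp-43A1 (302.3) and cyp-14A4 (169.9), both at tRNA genes, and without such peaks 0 of 141. C-type lectin genes had 3 of 237, at clec-126 (222.5), clec-57 (98.9) and clec-140 (82.7), and F-box A genes had 1 of 169, at fbxa-83 (126.5). C-type lectins were called as lower in the replicate 1 list alone (1 of 237, Fisher adjusted p = 0.0262), with the wide window (adjusted p = 0.0447) and with the nearest start at any distance (adjusted p = 0.0211). F-box A genes were called as lower with the nearest start at any distance (Fisher adjusted p = 0.0222). Without peaks at short RNA genes these lists had 1 of 237 and 0 of 169. No peak was found at genes for intestine (0 of 25), pharynx (0 of 15), pan-neuronal function (0 of 21), glia (0 of 13), major sperm proteins (0 of 31), TGF-beta signalling (0 of 18), Hox and cofactors (0 of 10) and the proteasome (0 of 33). In simulations, lists of 80 genes with 2 times the background share were called in 23.5% of draws at an unadjusted p of 0.05, and smaller lists were not simulated.

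**Figure D4:**
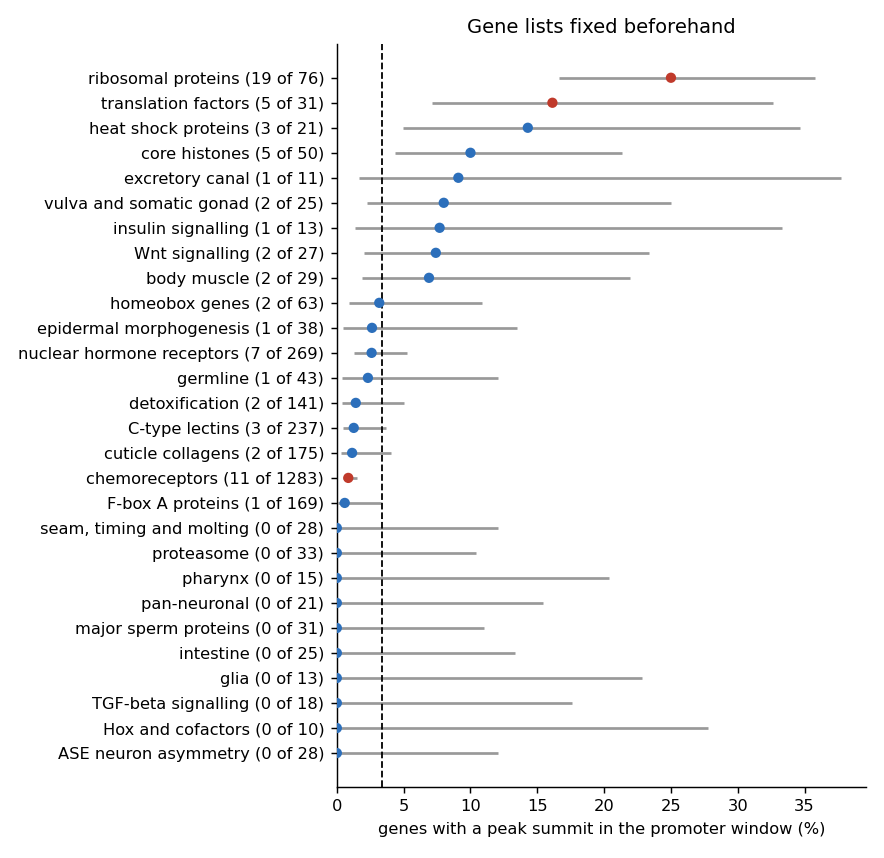
Share of the members of each fixed gene list with a reproducible summit in the promoter window, with 95% intervals. Ribosomal proteins had 25%.

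The X chromosome held more peaks than its length gives, and tRNA genes such as M02F4.t1 carried most of them. Of 1411 nuclear peaks, 351 (24.9%) lay on X, against 17.7% of nuclear length (fold 1.41, two-sided binomial p = 1.35e-11). Peaks at tRNA genes made up 201 of those on X, which holds 276 of the 612 tRNA genes. Without peaks at short RNA genes, X had 146 of 862 (16.9%, 95% interval 14.6 to 19.6), and the excess over length ended (fold 0.959, exact binomial p = 0.592). X holds 13.7% of protein-coding gene starts, and against that share all nuclear peaks had a fold of 1.82 (exact binomial p = 4.26e-29). The interval without peaks at short RNA genes also lay above the share of gene starts. tRNA genes on X had peaks at 222 of 276, and those on autosomes at 250 of 336 (two-sided Fisher adjusted p = 0.123). Chromosome III, with rpl-3 and tasp-1, had the most peaks away from short RNA genes, with 13 per Mb, and chromosome V had 6.07 per Mb. In the middle 50% of each autosome lay 629 of 1060 autosomal peaks (59.3%, two-sided binomial p = 1.29e-09). Gene starts had 55.7% there, and against that share p was 0.0159.

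**Figure D5:**
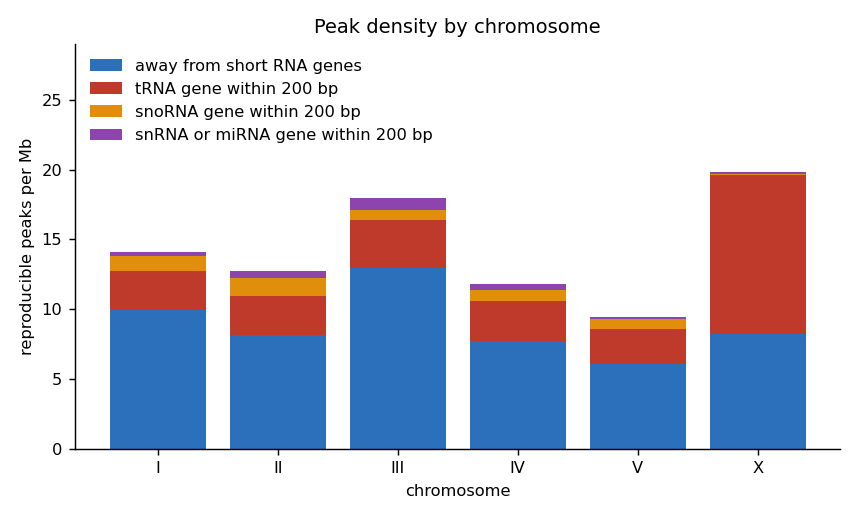
Peaks per Mb on each nuclear chromosome, with tRNA peaks apart from the others. X had 19.8 peaks per Mb.

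GAGA repeats were more frequent at summits than beside them. The word GAGAGA occurred in 17.3% of summit windows and 7.37% of flanking windows (two-sided exact McNemar adjusted p = 1.31e-15 over 15 motifs). Away from short RNA genes it occurred in 22.7% of summit windows, against 7.08%. The SMAD word GTCTAG had 6.31% against 1.35% (exact McNemar adjusted p = 6.27e-12), and it lost its excess without peaks at short RNA genes (-0.58 percentage points, adjusted p = 0.553). The CG-rich word GCGCGC had 5.60% against 0.921% (exact McNemar adjusted p = 5.37e-12). The KLF word had 4.96% against 1.35% (exact McNemar adjusted p = 5.44e-08), and the E-box CACGTG had 4.39% against 1.49% (adjusted p = 1.06e-05). In the 50% of peaks with the highest signal the E-box call ended (0.719 points against 2.91, exact McNemar adjusted p = 0.576).

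The trans-splice acceptor word TTTCAG was rarer at summits, at 6.02% against 17.6% (exact McNemar adjusted p = 7.11e-20). Tracts of T were also rarer, at 4.32% against 10.3% (exact McNemar adjusted p = 3.44e-09), and so was TATAAA, at 5.67% against 10.2% (adjusted p = 1.80e-05). The homeobox word TAATTA had 1.49% against 4.96% (exact McNemar adjusted p = 2.65e-07). The GATA word TGATAA had 7.09% against 9.85% (exact McNemar adjusted p = 0.0131), and the AP-1 word had 1.42% against 2.83% (adjusted p = 0.0163). The GATA call ended in the replicate 1 list alone (-1.20 percentage points against -2.76, exact McNemar adjusted p = 0.335). In the 50% of peaks with the highest signal the GATA deficit was larger but missed the threshold over fewer windows (-3.17 points, exact McNemar adjusted p = 0.0701). The AP-1 deficit stayed near its -1.42 points but missed the threshold without peaks at short RNA genes (-1.39, exact McNemar adjusted p = 0.133) and in windows of 100 bp to each side (-1.56, adjusted p = 0.0775). Shuffled summit windows keep the counts of single bases and of each pair of adjacent bases. Against them, GATA turned to an excess of 2.98 percentage points, T tracts to 1.98 and TATAAA to 2.27. Under that control the deficit of TTTCAG shrank from -11.55 to -2.48 percentage points (exact McNemar adjusted p = 0.0271), and the excess of GCGCGC shrank from 4.68 to 1.91 (adjusted p = 0.0284). The calls for KLF (0.992 points, exact McNemar adjusted p = 0.221), the E-box (1.56, 0.0525), the homeobox word (-1.06, 0.068) and AP-1 (-1.13, 0.067) ended. The ASE word GAARCC had 7.65% against 8.79% (exact McNemar adjusted p = 0.307). The CRE word, the forkhead word and the nuclear receptor half-site passed no threshold (exact McNemar adjusted p = 1, 0.164 and 0.107).

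Among 2080 words of 6 bases, 533 were more frequent at summits and 392 were less frequent. Against shuffled summit windows the balance turned, with 211 more frequent and 244 less frequent. CGAACC, which lies in box B of tRNA genes, had the smallest p (15.6% against 2.48%, exact McNemar adjusted p = 1.05e-34). ACCACT (15.9% against 3.12%), AGAGCG (13.5% against 2.20%), GTTCGA (18.99% against 5.88%) and AGACGC (11.8% against 2.27%) were more frequent too. AAAAAT (21.8% against 43.4%), AAAATT (16.6% against 35.4%), TTGAAA (11.8% against 28.1%), TCAAAA (11.4% against 25.9%) and TAAAAA (12.3% against 27.8%) were less frequent. Against shuffled windows AAAAAT (5.17 percentage points) and AAAATT (3.33) turned to an excess, while TTGAAA, TCAAAA and TAAAAA were no longer called. Without peaks at short RNA genes the calls for CGAACC (exact McNemar adjusted p = 0.205), ACCACT (0.0565) and GTTCGA (0.338) ended. The longer word CTGCGTCTC was joined, after the data had been seen, from words of 6 bases that were frequent at the 862 summits away from short RNA genes. It lay at 59 of these summits and in 4 flanking windows, and no p is given because the same windows chose the word. Those summits included the peaks at the histone methyltransferase gene set-16 (192), the myosin gene myo-6 (169.5), lin-66 (162.4), hsp-3 (142.2) and the bZIP gene cebp-1 (135.3).

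Neither die-1 (II:10061302-10067917) nor unc-119 (III:10902641-10908935), the usual rescue marker of worm transgenes, had a reproducible peak from 5000 bp before to 5000 bp after the gene. In the pooled relaxed list die-1 had 2 peaks, the highest with a signal of 52.7 at rank 3518 of 30000. unc-119 had 8 pooled peaks, the highest with 60.1 at rank 2586. The highest peak at die-1 had 57.8 in replicate 1 (rank 581 of 23789) and 63.0 in replicate 2 (rank 806 of 29268). Each was above the pooled 52.7, and whether both replicate peaks lay at the same site was not checked. The percentile of pooled peaks per kb among protein-coding genes was 25.4 for die-1 and 75.3 for unc-119. For die-1 it was 43.5 in replicate 1 and 53.7 in replicate 2, and for unc-119 it was 53.7 in replicate 1 and 71.0 in replicate 2.

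The lists on the older assembly ce10 gave similar sizes. The mitochondrial genome held 21 of 1483 reproducible ce10 peaks and 21 of the 1432 ce11 peaks. X held 24.8% of nuclear ce10 peaks and 24.9% of nuclear ce11 peaks.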

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

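For the tRNA and snoRNA pattern, the test of summit windows at tRNA genes without an identical copy and the use of ribosomal protein genes as a test of open chromatin were chosen only after the result was seen. The X chromosome and mitochondrial tests were also chosen only after the results were seen. The other tests had their predictions written before the values were known.

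tRNA and snoRNA genes led the nuclear peaks, and reads shared among identical tRNA gene copies could produce such peaks. tRNA genes without an identical copy had a peak in 52.1% of cases (73 of 140), and those with copies in 84.5% (399 of 472, two-sided Fisher p = 4.83e-14). Any summit within 200 bp counted, so some of the 73 may have counted through a summit at a neighbouring tRNA gene with copies. The 52.1% may be too high for that reason. The prediction was under 20% if shared reads were the cause and at least 50% if they were not. The 52.1% met the second limit, and the 95% interval of 43.9 to 60.3% lay above 20% but reached below 50%. The prediction named no interval, and with the interval required to clear 50% the explanations cannot be told apart by this test. Of all tRNA summit windows, 69.8% (303 of 434) had most of their 36-base words once in the genome, and the median window had 62.1% such words. Each 101 bp window also held sequence beside the gene, which can be unique even where the gene has copies. That share therefore does not exclude shared reads, which stay open for tRNA genes with copies. At tRNA genes without an identical copy, 93.5% of summit windows (58 of 62) had most of their 36-base words once in the genome. These genes were chosen for having no identical copy, and only exact words were counted. This test therefore cannot exclude reads shared with near copies. Of snoRNA summit windows, 98.7% (76 of 77) had most of their 36-base words once in the genome, which is against reads shared among exact repeats there.

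Promoter elements of RNA polymerase III were then sought at snoRNA genes, since that polymerase also transcribes tRNA genes, rpr-1, mrpr-1 and yrn-1. A box B word lay within 100 bp upstream of 35.1% of snoRNA genes with a peak and 4.46% of those without (odds ratio 11.6, two-sided Fisher p = 2.00e-11). None of these 77 snoRNA genes lay near a tRNA gene. Strongly transcribed open chromatin may be enriched whatever the antibody binds, and 25% of ribosomal protein genes had a peak. Without a strain that lacks the tag, that share leaves specific and unspecific enrichment such that they cannot be told apart.

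The X excess over length ended without peaks at short RNA genes, where X held 16.9% of peaks with a 95% interval of 14.6 to 19.6%. That interval holds the 17.7% of length and lies below the 24.9% of all nuclear peaks, which is what dense tRNA genes on X would give. It also lies above the 13.7% of protein-coding gene starts on X, so by that measure an excess remained, without a test of its own. Of the nuclear pooled relaxed peaks 14.7% lay on X, which is inside the interval. Against that background an excess cannot be told.

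Mitochondrial DNA carried 21 peaks in the reproducible list, and they were outside the nuclear comparisons. They covered 56.1% of the mitochondrial genome. High copy number of that genome could give such broad cover, but the control was not analysed here, so copy number and binding cannot be told apart. With 1 group in the design, no biological explanation was tested by a contrast of groups, and the promoter elements and the placement of tRNA genes were tested only as features of the genome sequence.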

How the results depend on the processing

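The settings without peaks at short RNA genes or mitochondrial peaks, and all settings of the snoRNA share, were chosen only after the results were seen, and all others were set before. Of the values compared with their main setting, 212 kept their direction and their side of the threshold (for counts, stayed within 1.5 times), 19 lost their call, 11 turned direction and 7 counts moved. The cause was not tested unless stated. Without peaks at short RNA genes, X fell to a fold of 0.959 over length, because dense tRNA peaks on X were removed by construction. In that setting the signal difference between promoters and other places turned to 0.00676, the words of 6 bases called fell from 925 to 488, and the SMAD word turned to -0.58 percentage points. In the 50% of peaks with the highest signal, the signal difference shrank to -0.0277. Some values kept their call but changed in size: the replicate correlation fell from 0.643 to 0.294 without short RNA and mitochondrial peaks, the tRNA fold fell from 98.95 to 47.3 at 500 bp, and the log2 odds ratio of ribosomal proteins fell from 3.31 to 2.10 against genes with a relaxed peak. The promoter fold fell from 1.48 to 1.13 against relaxed peaks. Among rises, the snoRNA fold went from 30.4 to 52.9 in the 50% of peaks with the highest signal. The GAGA excess went from 9.92 to 16.4 percentage points in windows of 100 bp to each side. Gene lists called numbered 3 in the main setting and 3 to 6 when either replicate was left out, and of the 3 called without replicate 1 core histones replaced translation factors. The wide promoter window gave 5 called lists, the nearest start at any distance gave 6, and a background of genes with a relaxed peak gave 1. Shuffled summit windows as the control gave 7 called motifs in place of 11, and 455 called words of 6 bases. Under that control GATA turned to 2.98 percentage points, T tracts to 1.98, TATAAA to 2.27, AAAAAT to 5.17, AAAATT to 3.33, TTGAAA to 0.638, TCAAAA to 0.851 and TAAAAA to 0.851, of which the last 3 were not called (exact McNemar adjusted p = 0.776, 0.645 and 0.645). Shuffling keeps the counts of single bases and of each pair of adjacent bases at the summit. The summit is richer in G and C than the flank (47.6 against 37.3%), so words rich in A and T had lower control shares by construction.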

Other observations

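The tRNA share, the gene lists, the box B test at snoRNA genes, the test of tRNA gene copies and the window test at snoRNA genes were set before their values were known. The counts at other RNA genes, the use of ribosomal protein genes as a test of open chromatin, the mitochondrial cover and the word CTGCGTCTC were chosen only after the results were seen. Some genes transcribed by RNA polymerase III, namely 472 of 612 tRNA genes, rpr-1, mrpr-1 and yrn-1, carried peaks, and no list of all such genes was tested. The annotated nuclear rRNA genes carried none, although the same polymerase transcribes the 5S genes among rRNA genes. Whether reads can be placed uniquely at rRNA genes was not checked, so the lack of peaks there decides nothing. The sls-2 genes, which another polymerase transcribes, carried peaks at 8 of 18, of which sls-2.9 was counted by a summit inside a tRNA gene. The 35.1% of snoRNA genes with a peak that had box B upstream is consistent with these snoRNA genes having such promoters of their own. Ribosomal protein genes with a peak (25%) have no such promoter known, so transcription by that polymerase does not cover every group. Peaks with the word CTGCGTCTC, such as those at set-16 and lin-66, lay in promoters in 29 of 59 cases, near the 49.1% of all peaks away from short RNA genes.

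A list of the same antibody in worms without the tag would separate peaks of DIE-1 from peaks of open chromatin, a question that the 25% of ribosomal protein genes with a peak leaves open. Reads of the control along the mitochondrial genome would test whether the 56.1% cover reflects copy number. Read mapping qualities at tRNA genes without an identical copy, 52.1% of which had a peak, would show whether shared reads added to them.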
